A study of Mus musculus with 6 samples.

How the data were processed

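RNA was sequenced from cultured neural progenitor cells, the dividing precursors of neurons and glia, of mice labelled as lacking p53, the tumour suppressor encoded by Trp53. Cells of 3 mice (62, 68 and 69) were grown for 4 days in stem cell medium with epidermal growth factor, fibroblast growth factor and heparin (the EF group, n = 3), which the series design names as the control. Cells of the same 3 mice were grown for 4 days with platelet-derived growth factor A (the PDGFA group, n = 3). Groups, mice and days were taken from the sample titles, per the labels. RNA was extracted with an RNeasy column, 1.3 ug of total RNA entered each library, and libraries were made with the NEBNext Ultra II kit E7770, per the labels' protocols. That kit does not mark strand, so reads of a gene and of an overlapping antisense gene are not separated. The molecule is labelled as polyadenylated RNA.

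The authors deposited 1 table of normalized signal, that is read counts per gene divided by 1 size factor per library, for 22057 genes named by symbol. FastQC, STAR and DESeq2 and the genome build mm10 (GRCm38) are listed per the submitters' processing notes, with no versions. The annotation release and the strand setting of the counting are not given in the sources used here. Each deposited value was divided by the smallest value above 0 of its library, and 100% of the values came out whole within 0.001, so whole reads were recovered. The recovered totals ran from 27270246 to 39601349 reads per library, and the implied size factors from 0.782 to 1.18. The lowest total over the 6 libraries was 10 reads per gene. Genes with fewer reads are not in the table.

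A gene was tested when its mean normalized count over the 6 libraries was at least 10, which kept 17068 genes and left out 4989. Values were tested as log2(normalized count + 1) with limma 3.58.1 (lmFit, and eBayes with a mean trend) in R 4.3.3, with the group as the only term, two-sided, and with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that scale, which understates the change of genes with few reads. All adjusted p-values of genes are from this limma fit unless another tool is named. Beside the limma counts, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 were run on the recovered reads. Means are given ± SD over 3 libraries, and SE belongs to the log2 fold change. The depth sets the precision of genes with few reads, and counting intervals cover counting error only, since the labels name no molecular identifiers.

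The 3 mice contribute to both groups, so the mouse numbers in the titles pair the libraries by animal. Deviations from the group means, compared between the 2 libraries of a mouse over the tested genes, had correlations of -0.091 for mouse 62, 0.11 for mouse 68 and -0.11 for mouse 69. The test without a block, the gene lists, the rule for named genes and all alternatives but the removal of abundant genes were chosen before the data were examined. The test with the mouse as a block was an alternative. No pair of libraries of a group agreed within sampling noise: chi-square per degree of freedom lay between 22.6 and 160, so none was counted as a repeat deposit. All 6 libraries had Y-linked transcripts (Ddx3y between 1452 and 2261) and low Xist (7.67 to 22.0).

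There were 34 lists of cell-cycle, signalling, metabolic and stress genes and of markers of the cell types a neural culture can hold. Each was tested against the other genes with camera (cameraPR, preset inter-gene correlation 0.01) on the moderated statistics, with Benjamini-Hochberg adjustment over the 34 lists. Camera with a correlation estimated from the data, and fry, which tests whether the members move on balance in 1 direction, were run beside it. The rule for named genes took Trp53 and the tested ligands and receptors of the epidermal, fibroblast and platelet-derived growth factor families. It took the 10 largest rises and the 10 largest falls among called genes that changed the same way in all 3 pairs and had a mean of at least 50 in the higher group, unnamed gene models left out. From each list came up to 2 called members that rose and 2 that fell with the smallest p, and up to 4 further called members where the list moved. Each called gene named, except Stard4, Insig1 and Tm7sf2, changed in the same direction in all 3 pairs. Some genes that the rule took are not reported here. Genes named outside the rule are said to be so. Coordinates are from GENCODE M21 (GRCm38), matched by symbol; 97.7% of the symbols were found in the gene name table of the reference.

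The tests were checked on simulated reads for PDGFA against EF with 200 changed genes. Reads were drawn from the EF means for both groups, with the library sizes of the 6 libraries and 1 dispersion per gene for both groups. In the data the median SD (log2) was 0.38 in EF and 0.172 in PDGFA, which the simulation does not copy. With so few changed genes the adjusted threshold is stricter than in the data, so recovery there can differ. At a 2-fold change limma recovered 17.0% of the 47 changed genes that passed the filter, at a 4-fold change 74.0% of 50, at a 16-fold change 95.7% of 46, and at a 1.5-fold change 0% of 48, over 16283 genes. It made 9 false calls; edgeR recovered 18.0%, 74.0%, 90.0% and 0% at the same folds. Alternatives covered the pseudocount, the filter, 3 other scalings, limma without trend or with robust variance, edgeR, DESeq2, the mouse block, and leaving out each library and each mouse. Removal of the most abundant and mitochondrially encoded genes was added after seeing the data.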

Results

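The series compared neural progenitor cells of p53-null mice after 4 days in medium with epidermal and fibroblast growth factors and heparin (EF) with cells of the same mice after 4 days with platelet-derived growth factor A (PDGFA). Its title concerns mitosis that goes wrong under a mitogen and the transformation of such cells. EF libraries held 30151469, 29653178 and 27270246 recovered reads for mice 62, 68 and 69, and PDGFA libraries 39601349, 34812800 and 38181689. The media differed in 2 ways at once, since one set of factors was taken away and another was added, so each comparison is of the 2 media. Between-library correlations of log2 values across genes, which are not independent replicates, were 0.949 to 0.970 within EF, 0.981 to 0.991 within PDGFA and 0.823 to 0.869 between the groups. The first principal component carried 79.0% of the variance and separated the groups. The median SD between the 3 libraries of a group was 0.38 (log2) in EF and 0.172 in PDGFA.

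Trp53 (chromosome 11, 69580359 to 69591873) was read in every library. Its normalized count was 2187, 1672 and 2383 in EF and 1122, 988.3 and 1099 in PDGFA for mice 62, 68 and 69. The group means were 2081 ± 367 and 1070 ± 71.6, a log2 fold change of -0.94 (SE 0.17, adjusted p = 0.00386), lower in all 3 pairs. The labels do not give the deleted part of the gene, so these reads check nothing about the genotype.

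Cells in PDGFA differed from cells in EF in 3720 genes that were higher and 3076 that were lower, of 17068 tested, with a fold of at least 2 in 2639 and 2063 of them. Genes of myelinating oligodendrocytes and of astrocytes were among the largest rises, and genes of dividing cells such as Pimreg, Hmmr and Neil3 among the largest falls. Enpp6, a marker of newly formed oligodendrocytes (chromosome 8, 46986887 to 47096762), had 5.36 ± 7.18 normalized counts in EF and 34550 ± 1929 in PDGFA, a log2 fold change of 13.18 (SE 0.83, adjusted p = 3.58e-05). Gfap, the intermediate filament of astrocytes, went from 36.2 ± 27.2 to 91000 ± 17540, and Mbp, a myelin protein, from 60.8 ± 48.2 to 79170 ± 24060. The complement gene C4b, Mag, Fa2h and Tmem163 were other large rises, with log2 fold changes of 10.61, 10.54, 9.72 and 9.36. Fa2h read 51.8 in the EF library of mouse 68 against 0.958 and 1.28 in those of mice 62 and 69, and its log2 fold change was 11.27 without EF 68, 8.89 without EF 62 and 8.999 without EF 69. Without EF 68 the log2 fold changes of Enpp6 and Mbp were 14.16 and 11.26, and without EF 62 those of Enpp6, Mbp, C4b and Mag were 12.23, 9.94, 9.89 and 9.80. Lgi4 had 2 EF reads in all and Slc14a1 had 3, so their ratios of 2120 (95% counting interval 586 to 17500) and 1270 (433 to 6150) are loose. The largest falls were Cpne7, Neil3, Cd93, Pimreg, Igfbp2, Tk1, Hmmr, Angpt2, Papln and Arhgef39, with log2 fold changes between -8.07 and -7.50. Igfbp2, which binds insulin-like growth factors, went from 29040 ± 11840 to 125.7 ± 60.2, and Tk1, thymidine kinase, from 1907 ± 1308 to 7.95 ± 5.44. Single libraries moved the ratios between the groups of Cd93, Papln and Tk1 by more than 1.5-fold. The log2 fold change of Cd93 was -8.63 without EF 62 and -7.34 without EF 69. That of Papln was -8.25 without EF 62 and that of Tk1 -7.05 without PDGFA 62.

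Of the called genes, 3716 rises and 3070 falls had the same direction in all 3 pairs. The groups did not overlap in 4979 higher and 4494 lower genes, where chance gives 10% of genes in both directions together. edgeR gave 3592 higher and 3263 lower, and DESeq2 3942 and 3746. Without the PDGFA library of mouse 68 the calls were 2245 higher and 1873 lower, and without both libraries of mouse 68 they were 1943 and 1333, with 1278 at least 2-fold lower. Without EF 62 they were 4271 and 3818, more than with all 6 libraries.

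**Figure D1:**
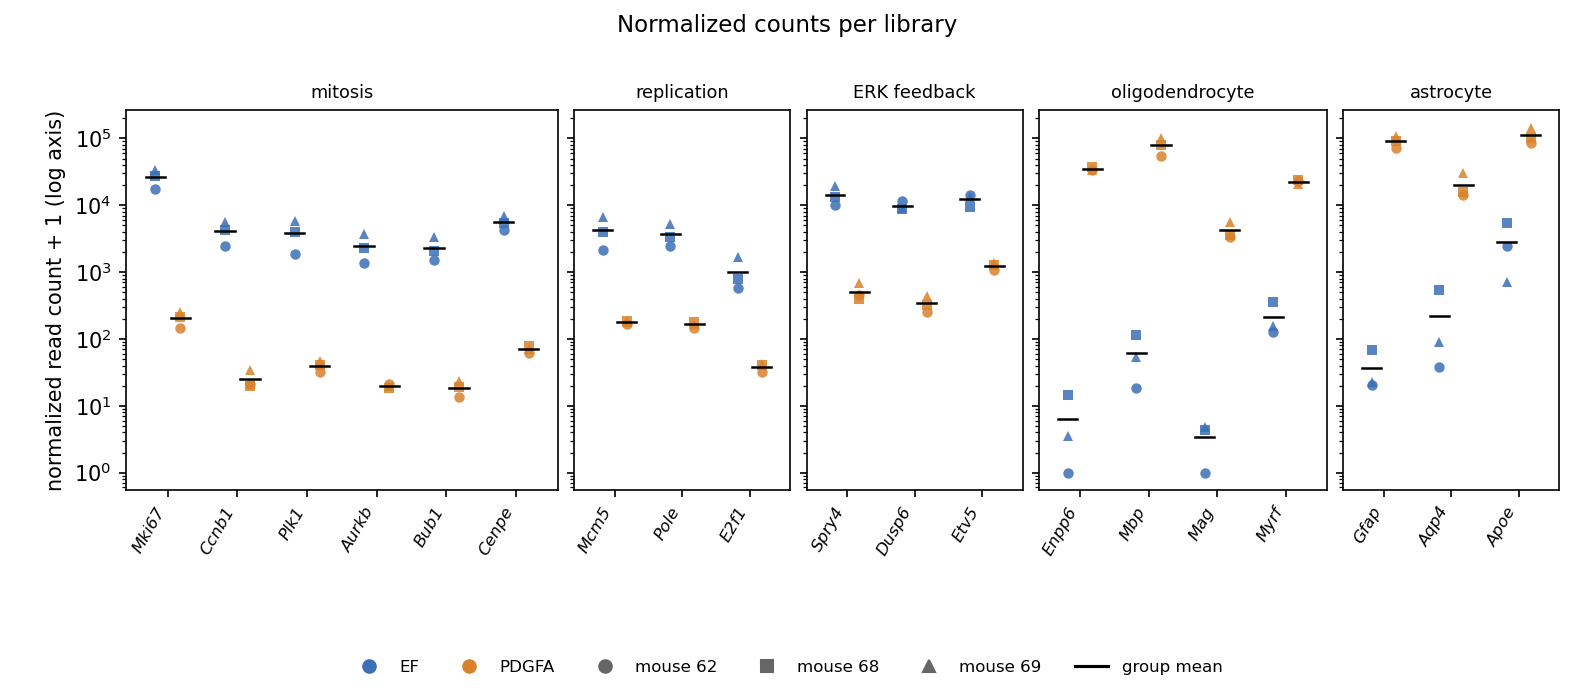
Normalized read count plus 1 per library on a log axis for genes of mitosis, DNA replication, ERK feedback, oligodendrocytes and astrocytes; blue is EF, orange is PDGFA, symbols are the 3 mice and bars are group means. Plk1 lies between 1884 and 5745 in EF and between 30.6 and 45.7 in PDGFA, while Enpp6 lies between 33220 and 36770 in PDGFA.

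Genes that carry cells through mitosis fell together. Of 25 genes of mitotic entry and of the G2 and M phases, 24 fell, with a median log2 fold change of -5.54. Mki67, the proliferation antigen (chromosome 7, 135689784 to 135716361), went from 26210 ± 8172 to 203.0 ± 55.3, a 129-fold lower mean (log2 fold change -6.99, SE 0.29, adjusted p = 1.12e-05). Ccnb1, the cyclin of mitotic entry, went from 4111 ± 1583 to 24.2 ± 7.77, and Top2a, which untangles chromosomes, from 19500 ± 6202 to 216.7 ± 42.1. Plk1, a mitotic kinase singled out after its values were seen, went from 3884 ± 1934 to 38.8 ± 7.66. Of 43 tested genes of the kinetochore, which ties chromosomes to the spindle, and of its checkpoint, 39 fell, with a median of -4.01. Among them Bub1, a checkpoint kinase, had a log2 fold change of -6.89 (SE 0.35), Cenpe, a kinetochore motor, -6.28 (SE 0.22), Knl1 -5.79 (SE 0.22) and Ttk -5.63 (SE 0.31), each with an adjusted p of at most 2.52e-05. Of 27 spindle motors and microtubule organisers 24 fell, with a median of -4.36, including Kif23 (-6.59) and Prc1 (-5.63).

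Of 18 genes of cytokinesis and the chromosomal passenger complex 16 fell, with a median of -5.41. Aurkb, the kinase of that complex, went from 2463 ± 1196 to 18.8 ± 1.59. Septin7, a cytoskeletal filament protein also used outside division, was the member that rose, from 8612 ± 1234 to 17800 ± 1899 (adjusted p = 0.00235). Of 21 cohesin and condensin genes 14 fell and 2 rose, with a median of -0.99. The falls were led by Ncapg (-6.04) and Esco2 (-6.13), and Mau2, a cohesin loader, rose by 0.66. The other riser, Esco1 (0.52, adjusted p = 0.028), was not called with the mouse as a block (0.0739); its adjusted p ran from 0.00697 to 0.27 over the alternatives, and it was also not called without EF 68 or without any single PDGFA library (0.069 to 0.117). Of 25 centrosome genes 17 fell, with a median of -1.19, among them Aspm (-6.50) and Plk4, the kinase that starts centriole duplication (-4.01). Counts adjusted over the list alone were equal to these for the 6 lists. The lists are not independent, since Kif23, Kif20a, Prc1, Racgap1 and Ckap2 are in both the spindle and the cytokinesis list. Plk4 is in both the cytokinesis and the centrosome list. In camera the adjusted p was 1.08e-17 for mitotic entry, 5.31e-22 for the kinetochore, 6.57e-17 for the spindle, 3.61e-12 for cytokinesis, 2.87e-06 for cohesin and condensin and 3.06e-08 for the centrosome. None of these calls held with an estimated correlation (0.467 to 0.771 for these lists), where each had an adjusted p = 0.451. That correlation is estimated from 6 libraries, and the smallest unadjusted p of that camera test over the 34 lists was 0.0355. A missing call in it therefore decides little, here and for the lists below. In fry the adjusted p ran from 0.000731 to 0.00473.

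Genes of DNA replication fell as well. Of 45 replication genes 44 fell, with a median log2 fold change of -2.68. Mcm5, a part of the replicative helicase, went from 4295 ± 2304 to 176.7 ± 11.6, Pole, a replicative polymerase, from 3694 ± 1410 to 163.8 ± 17.7, and E2f1, a transcription factor of S phase, from 1007 ± 570 to 37.3 ± 5.86. Of 37 genes of homologous recombination and Fanconi anaemia repair 34 fell, or 35 when adjusted over the list alone, with a median of -2.21, led by Fancd2 (-5.45, SE 0.24) and Fanca (-5.55, SE 0.28). Rad51d was the member that rose (0.57, adjusted p = 0.0246). It was not called with the mouse as a block (0.0724; 0.00325 to 0.233 over the alternatives), nor without EF 68 or any single PDGFA library (0.0606 to 0.106). All 17 tested members of the histone list, drawn up for replication-dependent histones, fell, also when adjusted over the list alone, with a median of -3.30. H3c3 went from 5088 ± 2262 to 47.6 ± 13.1. Histone genes are near-identical copies whose transcripts mostly lack a poly(A) tail, so values of single histone genes are uncertain. The camera adjusted p was 2.13e-18 for replication, 3.28e-16 for repair and 4.13e-12 for histones. With an estimated correlation each had an adjusted p = 0.451.

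Of 18 G1 cyclins, their kinases and inhibitors, 9 fell and 4 rose, also when adjusted over the list alone, with a median of -0.87. Ccnd2 and Ccnd1, the D-type cyclins that answer growth factors, went from 57770 ± 6426 to 2139 ± 715 and from 53840 ± 23100 to 1692 ± 426. Cdk6, their partner kinase, fell by 3.68 on the log2 scale. Rb1, the retinoblastoma protein that restrains S phase, and the inhibitor Cdkn2b rose by 0.96 and 1.30. The list had a camera adjusted p = 0.0311, and adjusted p = 0.625 with an estimated correlation. Without EF 68 (adjusted p = 0.0521) or EF 69 (adjusted p = 0.0509) the list was not called, in a range of 0.00329 to 0.0521 over the alternatives.

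Targets and feedback inhibitors of ERK signalling fell. Of 24 such genes 18 fell and 1 rose, or 18 and 2 when adjusted over the list alone, with a median of -2.02. Spry4 went from 14480 ± 4838 to 507.6 ± 154, Dusp6, a phosphatase of ERK, from 9791 ± 1407 to 340.9 ± 94.9, and Etv5, a transcription factor, from 12270 ± 2597 to 1241 ± 140. Spry1 fell by 3.70 (SE 0.12, adjusted p = 7.92e-06). Emp1 was the member that rose (1.73, adjusted p = 0.0258), and it was not called without EF 68 or any single PDGFA library (adjusted p 0.0559 to 0.0816; 0.0051 to 0.124 over the alternatives). The camera adjusted p was 1.04e-07, and adjusted p = 0.451 with an estimated correlation. Of 24 immediate early genes 9 fell and 1 rose (9 and 3 adjusted over the list alone, 8 and 2 with the mouse as a block), with a camera adjusted p = 0.097, which became 0.0356 without PDGFA 69 (0.0356 to 0.185 over the alternatives). Dusp1 fell by 2.78 and Ier2 by 1.98. Fos rose by 1.73 (adjusted p = 0.0163), and was not called without EF 69 (adjusted p = 0.0503; 0.00014 to 0.06 over the alternatives).

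The receptors and ligands of the factors in the media moved in both directions. Of 20 tested members 7 rose and 6 fell (8 and 8 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.99, direction up, with a mean of 0.51 and a median of -0.27). Egfr, the receptor of epidermal growth factor (chromosome 11, 16752203 to 16918158), went from 28910 ± 2928 to 4975 ± 2231, a log2 fold change of -2.62 (SE 0.29, adjusted p = 0.00045). Fgfr1 fell by 0.84 (adjusted p = 0.00505), and Fgfr2 rose by 2.72 (SE 0.20, adjusted p = 6.8e-05). Pdgfrb rose from 21.9 ± 20.3 to 814.7 ± 95.8, and Pdgfa itself from 353.5 ± 86.8 to 2735 ± 92.6 (adjusted p = 5.17e-05). Tgfa, a ligand of Egfr, rose by 3.30 and Hbegf, another, fell by 1.66. The EF library of mouse 68 held 1360 counts of Tgfa against 289.2 and 254.4 in those of mice 62 and 69, and without it the log2 fold change was 4.07. That of Pdgfrb was 6.24 without EF 68 and 4.95 without EF 62.

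Pdgfra, the receptor of PDGFA (chromosome 5, 75152292 to 75198215), read 860.9, 14130 and 533.1 in EF for mice 62, 68 and 69, and 13600 ± 4917 in PDGFA. Its log2 fold change was 2.79 (SE 1.11, adjusted p = 0.0823), higher in all 3 pairs. The adjusted p was 0.0217 with the mouse as a block and 0.00052 without EF 68, in a range of 0.00052 to 0.36 over the alternatives. Its log2 fold change was 4.25 without EF 68 and 1.89 without EF 69. Erbb2 had a log2 fold change of -1.02 (adjusted p = 0.0755), which was called with the mouse as a block (0.0124) and without EF 62 (0.00656), in a range of 0.00656 to 0.333. Erbb3 (2.21), Erbb4 (1.95), Fgf2 (1.24), Fgf1 (-1.23), Fgfrl1 (-0.77) and Pdgfb (-2.24) passed the threshold, and each lost its call without PDGFA 68, with adjusted p of 0.134, 0.066, 0.0596, 0.0789, 0.0735 and 0.0769. Over the alternatives the adjusted p ran from 0.0048 to 0.194 for Erbb3, from 0.00156 to 0.124 for Erbb4, from 0.00325 to 0.111 for Fgf2, from 0.00618 to 0.106 for Fgf1, from 0.0013 to 0.18 for Fgfrl1 and from 0.00388 to 0.0869 for Pdgfb. Erbb3 was also not called without EF 62 (0.0942), EF 69 (0.106), PDGFA 62 (0.125) or PDGFA 69 (0.0742). Without EF 68 the log2 fold changes of Erbb3 and Erbb4 were 3.03 and 2.55. Erbb4 was also not called without EF 62 (0.0528), EF 69 (0.0521) or PDGFA 62 (0.0673), and Fgf1 without EF 62 (0.065), EF 69 (0.0507) or PDGFA 69 (0.0754). Fgf2 was also not called without EF 69 (0.0501), PDGFA 62 (0.108) or PDGFA 69 (0.0547), and Fgfrl1 without PDGFA 69 (0.0527). With the mouse as a block Fgf2 was not called (0.0546). Egf, Areg, Fgf13, Fgfr3 and Pdgfc had adjusted p of 0.831, 0.276, 0.0563, 0.335 and 0.423; without EF 62, Fgf13 (0.0111; 0.0111 to 0.264 over the alternatives) and Fgfr3 (0.0268; 0.0268 to 0.909) were called. The log2 fold changes of Egf and Pdgfc changed sign without EF 62, from -0.10 to 0.17 and from 0.39 to -0.05. Without PDGFA 68 that of Egf was 0.011.

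**Figure D2:**
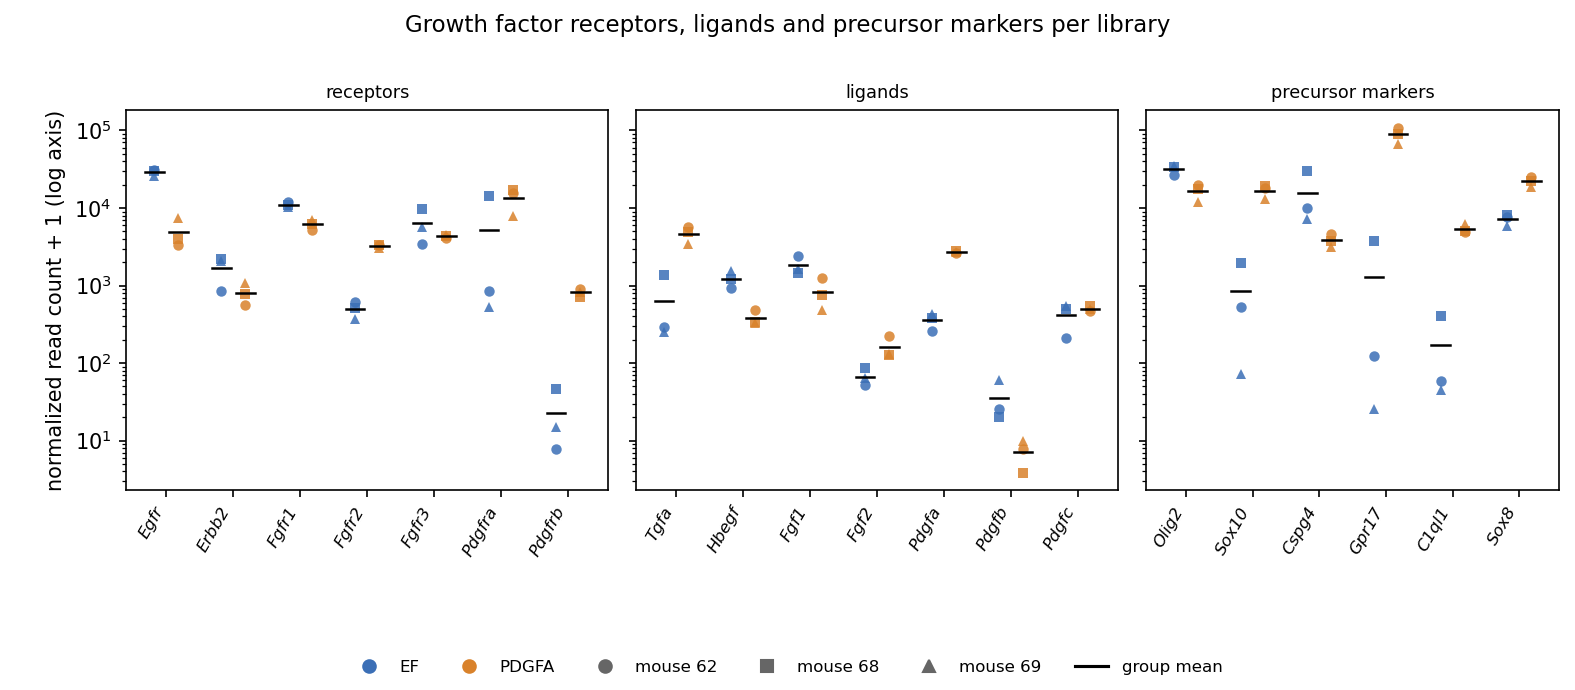
Normalized read count plus 1 per library on a log axis for growth factor receptors, ligands and oligodendrocyte precursor markers; blue is EF, orange is PDGFA, symbols are the 3 mice and bars are group means. The EF library of mouse 68 holds 14130 counts of Pdgfra against 860.9 and 533.1 in the other EF libraries.

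Markers of maturing oligodendrocytes rose. Of 26 tested members 22 rose and 2 fell (24 and 2 adjusted over the list alone), with a median log2 fold change of 4.96, which was the same with Mog set to its bound. Mog, a myelin surface protein singled out after its values were seen, was at 0 in all EF libraries and at least 24.8-fold higher in PDGFA, against a floor of 3 counts over the group. Cnp, an enzyme of myelin, went from 2528 ± 540 to 76130 ± 5427, Sirt2 from 2320 ± 478 to 62960 ± 3258, Bcas1 from 450.4 ± 164 to 58830 ± 1602, and Myrf, the transcription factor of myelin genes, from 212.0 ± 126 to 22580 ± 1861. Trf, transferrin, fell from 2800 ± 17.7 to 400.1 ± 84.3. Car2 fell by 1.56 and was not called without PDGFA 68 (adjusted p = 0.051; 0.00016 to 0.126 over the alternatives). The camera adjusted p was 3.61e-12, and adjusted p = 0.451 with an estimated correlation.

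Markers of oligodendrocyte precursors went both ways, with 9 of 26 higher and 7 lower (9 and 9 adjusted over the list alone, 12 and 8 with the mouse as a block), a median of 0.85 and a camera adjusted p = 0.679. Without EF 68 the adjusted p was 0.0561, and without both libraries of mouse 68 the list was called higher, with a median of 1.196 and an adjusted p = 0.0216 (0.0216 to 0.974 over the alternatives). C1ql1 rose by 5.71 and Sox8 by 1.61, while Xylt1 fell by 2.24 and Epn2 by 1.34. Of members chosen after their values were seen, Sox10 went from 853.0 ± 983 to 16630 ± 3248, Gpr17 from 1283 ± 2095 to 88740 ± 21170 and Olig2 from 31880 ± 4438 to 16370 ± 4071. Cspg4, also chosen so, went from 15780 ± 12530 to 3843 ± 759, and was not called without PDGFA 68 (adjusted p = 0.0668) or PDGFA 69 (adjusted p = 0.0834), in a range of 0.000187 to 0.0834. In EF the library of mouse 68 held more of Sox10, Gpr17 and Cspg4 (1957, 3702 and 30160) than those of mouse 62 (530.5, 122.6 and 9962) and mouse 69 (71.6, 24.3 and 7218). Without EF 68 the log2 fold changes of Sox10, Gpr17, C1ql1 and Cspg4 were 6.38, 10.60, 6.70 and -1.16. Without EF 69 those of Sox10, Gpr17 and C1ql1 were 4.01, 7.01 and 5.10.

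Astrocyte markers rose in 15 of 27 members, or 16 adjusted over the list alone, and the other 12 did not pass, with a median of 1.41. Apoe, a lipid carrier, went from 2870 ± 2414 to 111100 ± 30560, Clu from 309.1 ± 302 to 15810 ± 9040, and Gja1, the gap junction protein of astrocytes, from 2010 ± 1027 to 32760 ± 13400. Aqp4, a water channel chosen after its values were seen, went from 219.4 ± 271.5 to 20020 ± 9031. Without EF 68 the log2 fold changes of Apoe, Clu and Aqp4 were 6.37, 6.72 and 8.32 in place of 5.69, 5.96 and 7.26, while that of Apoe was 4.89 without EF 69 and that of Aqp4 6.42 without EF 62. The camera adjusted p was 1.04e-05, and adjusted p = 0.54 with an estimated correlation. Of 28 neuroblast and neuronal markers 10 rose and 2 fell, also when adjusted over the list alone, with a median of 0.70. Map1b and Mapt, microtubule-binding proteins, rose from 4694 ± 1226 to 65070 ± 3724 and from 1588 ± 731 to 18820 ± 1174, and Dcx, a marker of migrating neuroblasts, from 130.8 ± 186 to 4934 ± 941. In EF, Dcx read 24.9, 345.6 and 21.7 for mice 62, 68 and 69, and its log2 fold change of 6.37 was 7.65 without EF 68, 5.78 without EF 62 and 5.68 without EF 69. Sox11 and Elavl4 fell by 1.47 and 1.58. The list had a camera adjusted p = 0.0311, adjusted p = 0.759 with an estimated correlation and 0.0668 in fry. It was not called without EF 62 (0.146), EF 69 (0.0762) or PDGFA 68 (0.0875), in a range of 0.000841 to 0.18 over the alternatives.

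Markers of neural stem cells and radial glia were mixed, with 7 of 28 higher and 11 lower (8 and 11 adjusted over the list alone) and a camera adjusted p = 0.176. In DESeq2 the list was called lower, with a median of -0.36 and an adjusted p = 0.0401 (0.0401 to 0.415 over the alternatives). Hes1, a Notch target, fell by 3.10 and Hes5, another, rose by 1.60. Nes, the intermediate filament nestin, chosen after its values were seen, went from 33680 ± 13560 to 2575 ± 917. Sox2, also chosen so, rose by 0.68 (adjusted p = 0.0291), and was not called without EF 68 or any single PDGFA library (adjusted p 0.0547 to 0.115; 0.0076 to 0.188 over the alternatives).

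Genes of glycolysis and of the cytosolic ribosome fell as groups, while few genes of cholesterol synthesis were called. Of 29 genes of glycolysis and the hypoxia response 19 fell and 1 rose (20 and 2 adjusted over the list alone), with a median of -0.99. Ldha, lactate dehydrogenase, went from 15460 ± 3343 to 3512 ± 297, and Hk2, a hexokinase, from 2361 ± 356 to 284.8 ± 150. Hk1, another hexokinase, rose by 0.75 (adjusted p = 0.0358), and was not called without EF 62, EF 69 or any single PDGFA library (adjusted p 0.0566 to 0.123; 0.00946 to 0.191 over the alternatives). The camera adjusted p was 4.73e-05, and adjusted p = 0.451 with an estimated correlation. Of 25 genes of cholesterol synthesis 6 fell, or 2 adjusted over the list alone and 4 with the mouse as a block, and 19 did not pass, with a median of -0.77. Dhcr7, an enzyme of the last step of the synthesis, fell by 1.56 (adjusted p = 0.0284), and was not called without EF 68 (0.0834), EF 69 (0.0813), PDGFA 68 (0.0792) or PDGFA 69 (0.1), in a range of 0.000407 to 0.206. The called members Stard4, Insig1 and Tm7sf2 were higher in PDGFA in mouse 62, and none of these was called without EF 68, EF 69, PDGFA 68 or PDGFA 69 (0.102 to 0.157), nor Stard4 without PDGFA 62 (0.0612). Over the alternatives the adjusted p ran from 0.000616 to 0.267 for Stard4, from 0.00207 to 0.276 for Insig1 and from 0.00756 to 0.271 for Tm7sf2. The list had a camera adjusted p = 0.0055, adjusted p = 0.78 with an estimated correlation and 0.279 in fry, and was not called without EF 68 (0.0662) or EF 69 (0.0554), in a range of 6.44e-12 to 0.166. Of 50 cytosolic ribosomal protein genes 28 fell, or 34 adjusted over the list alone and 14 with the mouse as a block, with a median of -0.52. With libraries left out the median ran from -0.60 without both of mouse 68 to -0.33 without both of mouse 69. It was -0.38 without EF 69. Rpl12 fell by 1.01 (SE 0.18) and Rps6 by 0.74 (SE 0.14). The camera adjusted p was 4.27e-08, with adjusted p = 0.625 with an estimated correlation; ribosomal protein genes have many processed pseudogenes, so single values are uncertain.

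The other lists were not called. Of 27 p53 target genes 9 rose and 9 fell (9 and 10 adjusted over the list alone), with a camera adjusted p = 0.755 and a median of -0.08. Fas rose by 4.16 and Ccng1 by 1.29, while Plk2 fell by 3.53 and Plk3 by 1.75. Of members chosen after their values were seen, Cdkn1a, the cell-cycle inhibitor p21, fell by 2.03 (adjusted p = 0.013; 0.0529 without PDGFA 68, and 8.58e-05 to 0.0541 over the alternatives), and Mdm2 read 1856 ± 267 and 2111 ± 39.6 (adjusted p = 0.316). Of 28 genes of the BCL2 family and caspases 7 rose and 6 fell (adjusted p = 0.772), among them Bmf (2.70) and Bcl2 (-0.73). Of 29 stress response genes 1 rose and 9 fell, with a camera adjusted p = 0.0812, which was 0.041 with the mouse as a block, 0.0442 without EF 62 and 0.0361 without EF 68 (0.0276 to 0.136 over the alternatives). Dnajb9 rose by 1.36 and Mthfd2 fell by 3.30. These counts were equal when adjusted over the list alone for the BCL2 and stress lists.

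Ependymal and cilium genes rose in 8 and fell in 2 of 18 (adjusted p = 0.0812; 0.0381 without PDGFA 62, and 0.0381 to 0.0992 over the alternatives), with Cfap44 at 4.43 and Hydin at -3.22 (-3.86 without PDGFA 68). Of 37 extracellular matrix genes 8 rose and 15 fell (adjusted p = 0.151, and 0.0371 with a median of -0.99 in DESeq2, in a range of 0.0371 to 0.422), with Bgn at 6.22 and Lama4, a laminin chain, at -5.55. Of 21 Notch and Hedgehog genes 5 rose and 7 fell (adjusted p = 0.386), with Jag1, a Notch ligand, at -3.31. Of 24 targets of BMP, TGF-beta and Wnt 10 rose and 6 fell (adjusted p = 0.472), with Id4 at 6.24 and Bmp7 at -3.48. Of 22 interferon genes 4 rose and 4 fell (adjusted p = 0.915), with Gbp2 at 4.52 and Gbp3 at -2.79; the median was -0.12 and fry pointed up. Of 12 class I antigen presentation genes 2 rose and 3 fell (2 and 5 adjusted over the list alone; adjusted p = 0.426), with Nlrc5 at 5.69 and H2-K1 at -2.69. Of these lists, ependymal, matrix, Notch, BMP and interferon counts were equal when adjusted over the list alone.

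Many markers of cells from outside the neural lineage had too few reads to be tested: 10 of 20 endothelial, 12 of 24 pericyte and 5 of 23 microglial markers were tested. Of the 10 endothelial markers 2 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.721), with Kdr at 61.8 ± 27.0 in EF and 517.2 ± 135 in PDGFA. Of the 12 pericyte and mesenchymal markers 3 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.772), with a median of -0.91 while the mean was 0.47 and fry pointed up. That list shares Pdgfra and Cspg4 with the oligodendrocyte precursor list, so it does not measure cells from outside the neural lineage alone. Among the microglial markers P2ry12, which fell from 23.25 ± 18.6 to 5.01 ± 1.99, was called (adjusted p = 0.0484) but not with the mouse as a block (0.059), over the list alone, or without EF 68 or any single PDGFA library (0.0668 to 0.165), in a range of 0.0279 to 0.204; the list had an adjusted p = 0.789. Of 9 mitochondrially encoded genes 1 rose (adjusted p of the list 0.789). It was mt-Nd5 (0.76, adjusted p = 0.0424), not called over the list alone, with the mouse as a block (0.0956; 0.00504 to 0.205 over the alternatives), or without EF 62, EF 69 or any single PDGFA library (0.0614 to 0.136).

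**Figure D3:**
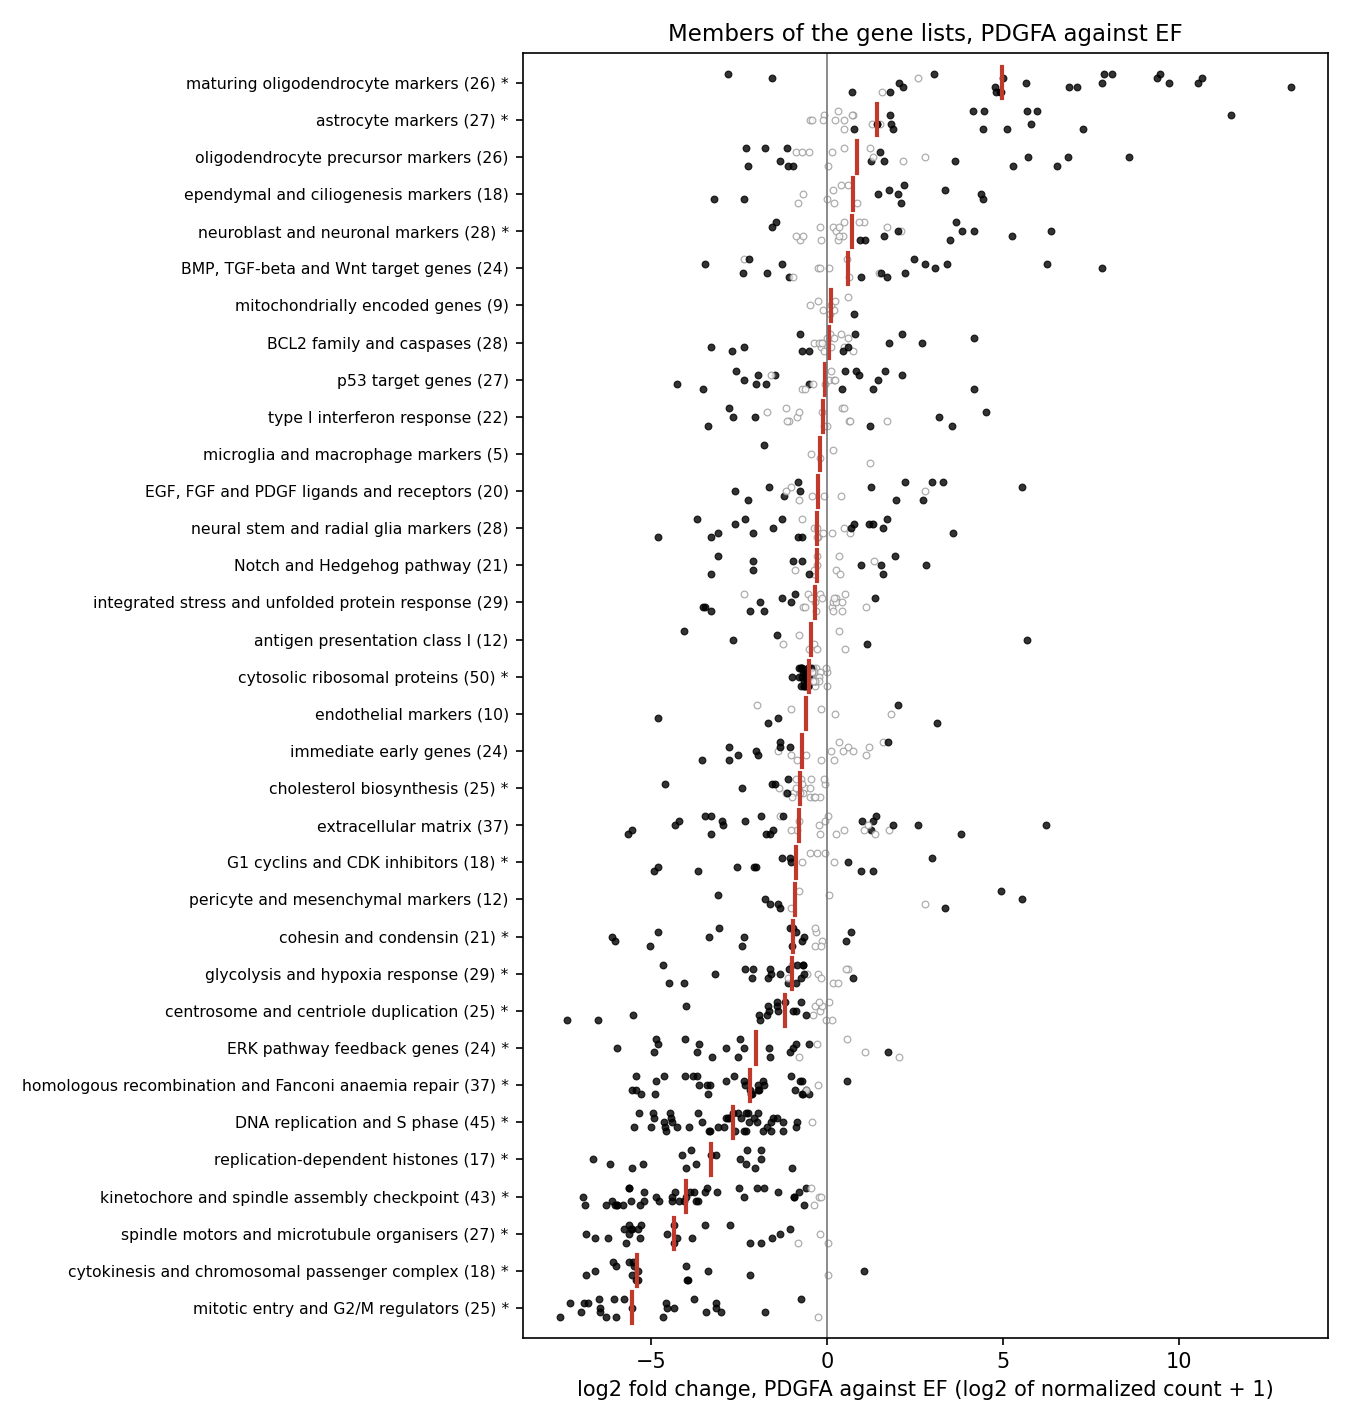
Log2 fold change of PDGFA against EF (horizontal axis) of each tested member of the 34 gene lists (vertical axis, number of members in brackets); filled points passed the adjusted p of 0.05, open points did not, red bars are list medians and a star marks lists past the threshold in camera with a preset correlation. Medians run from -5.54 for genes of mitotic entry and of the G2 and M phases to 4.96 for maturing oligodendrocyte markers.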

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

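The removal of the most abundant genes was chosen only after the data were seen. Counts of genes stayed within 1.5 times the reported ones under every pseudocount, filter, scaling and tool tried, and no called gene changed sign there or when libraries were left out. The share of higher genes among the calls ran from 51.0% to 59.3%, against 54.7% as reported. With the mouse as a replicate block 3213 genes were higher and 2626 lower, of which 3123 and 2554 were among those reported. Apart from the genes and lists named in the report, and Insig1 and Tm7sf2, which lost their calls, the block changed no call of a named gene or list. Leaving out libraries moved counts most, and not only by leaving fewer samples. Without EF 62 the calls rose to 4271 higher and 3818 lower. Without a single PDGFA library they fell to between 2245 and 2620 higher. The median SD was 0.38 (log2) in EF and 0.172 in PDGFA, and whether this set the difference was not tested. With libraries left out, genes higher ran from 1943 to 4271 and those lower from 1333 to 3818. Those at least 2-fold lower ran from 1278 to 2255. The low ends were without both libraries of mouse 68, where 47.4% of the reported calls were kept.

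With an estimated correlation camera called 0 lists higher and 0 lower against 3 and 14, and fry called 19. In that camera test 1 list had an unadjusted p under 0.05, and it was 0.0355. The correlation is estimated from 6 libraries, so these missing calls decide little about whether a list moved. Lists uncalled in camera that fry called were ependymal (adjusted p = 0.00745), immediate early (0.0235), Notch and Hedgehog (0.0358) and stem cell genes (0.0396), while the neuronal (0.0668) and cholesterol (0.279) lists were called in camera alone. Medians of uncalled lists that changed sign were 0.028 without a filter for growth factor ligands and receptors, and, at a mean of at least 50, 0.074 for p53 targets, 0.228 for endothelial, 0.037 for pericyte and 0.41 for interferon genes, where fewer genes are tested. Quantile normalization gave 0 for mitochondrially encoded genes, and the cause was not tested. With libraries left out, uncalled medians ran from -0.16 to 0.049 for p53 targets, -0.018 to 0.10 for the BCL2 family, -0.36 to 0.048 for microglial markers, -0.64 to 0.30 for interferon genes and -0.11 to 0.40 for mitochondrially encoded genes. Uncalled lists also passed the threshold without a filter (ependymal and stress response genes, adjusted p = 0.0449 for each), in edgeR (stress response, 0.0408), in DESeq2 (stem cell markers, 0.0401, and matrix genes, 0.0371), and without both libraries of mouse 62 (ependymal, 0.0437, and stress response, 0.0348), mouse 68 (stress response, 0.0276, and precursor markers, 0.0216) or mouse 69 (immediate early genes, 0.0405). The log2 fold change of Egf with libraries left out ran from -0.27 to 0.17 and that of Pdgfc from -0.048 to 0.65. In simulated reads 3 libraries per group with 200 changed genes recovered 0% of genes changed 1.5-fold and 17.0% at 2-fold. The data had 6796 calls, which eases the adjusted threshold, so these shares need not hold for the real comparison.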

Other observations

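The lists and the other scalings were planned, but the use of the kinetochore list to test scaling, abundant genes and the change of medium, all tests of the EF library of mouse 68, and the scan of gene families were chosen only after the result was seen.

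The fall of cell-cycle genes and rise of oligodendrocyte genes in PDGFA was set against technical explanations. Over 3 other scalings, edgeR and DESeq2 the median log2 fold change of the kinetochore list was at most -4.001. That of the maturing oligodendrocyte list was at least 4.86. All of these keep the median of all genes near 0 (-0.052 to -0.005), so they test only the move relative to other genes, which stayed. Without the most abundant genes the 2 list medians were -4.01 and 4.96, so they did not depend on those genes. No library (0 of 6) had only one of the 2 changes of medium, so loss of epidermal and fibroblast growth factor and gain of PDGFA cannot be told apart. Neither a change of state of the cells nor a change in which cells were present was tested. Of the 10 splits of the 6 libraries, 1 (the real one) called 6796 genes and the highest other called 0 in limma and in edgeR. The others gave 29 to 305 genes at an unadjusted p under 0.05 in limma. Each other split mixes EF and PDGFA libraries, so the difference between the media widens the spread within its groups. The splits therefore cannot test chance, and 10 splits are also too few for a share under 0.05.

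In the EF library of mouse 68 the excess of Pdgfra over the mean of the other 2 EF libraries was 104% of its excess in PDGFA. Over the 265 genes at least 32-fold higher in PDGFA than in those 2 libraries, the median of this share of the excess was 1.44%, which argues against reads or cells of a PDGFA culture. The precursor list had a median log2 ratio of 1.29 (random lists of like expression gave -0.10 to 0.19). It lay 1.26 above the median of those random lists, a difference that no factor per library changes, which argues against depth or scaling, and 13 of 26 members were at least 2-fold above both other EF libraries. Without Pdgfra and Gpr17 the median was 1.11. A higher share of precursor-like cells may explain this, but astrocyte markers (1.08) and cholesterol genes (0.97) were also higher there. Pericyte markers were too (0.93), though that list shares Pdgfra and Cspg4 with the precursor list. A higher level per cell stays open.

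The lower ribosomal protein genes in PDGFA were tested against gene length and scaling. The 50 members had a median transcript length of 809 bases against 2284 for all tested genes with a known length, and 0% of 10000 random lists matched on length and expression had a median as low, the matched lists lying between -0.25 and 0.17. The highest median over 3 other scalings, edgeR and DESeq2 was -0.52. All of these keep the median of all genes near 0 (-0.052 to -0.005). They therefore test only the fall relative to other genes and cannot exclude scaling for the level per cell. Reads shared with pseudogenes were not tested and no biological explanation was tested.

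Since the series concerns defective mitosis, gain or loss of whole chromosomes between cultures of 1 group was tested as a hypothesis. The largest absolute chromosome median of a library against the other 2 of its group was 0.124, reached on chromosome X in EF 62 and on chromosome 1 in EF 69, both with a median of -0.12. Of 120 medians, 9 lay beyond the limit that 0.1% of random gene sets exceed: chromosomes X, 15, 12, 1 and 11 in EF 62, 1 in EF 69, 1 and 11 in PDGFA 69 and 4 in PDGFA 68. A simulated 1.5-fold gain of 1 chromosome gave 0.556 in PDGFA 62 and 0.603 in EF 62 when in all cells, and 0.178 and 0.231 when in 30% of cells, so a gain of that extent was not seen. Changes in a smaller share of cells stay open, and a change shared by all cultures of a group would not show in this test.

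A scan of 255 families of genes with a shared name stem found 16 past the threshold in camera, of which 7 had no gene in the lists above, and 0 with an estimated correlation (adjusted p of 0.985 for each of the 7). Of 20 nucleoporin genes 16 fell, with a median of -1.08, including Nup107 (-1.41) and Nup210 (-1.83), chosen after their values were seen. Small nucleolar RNA genes (12 of 39 fell) and proteins of the large mitochondrial ribosomal subunit (Mrpl, 13 of 49 fell) were lower in camera, the latter with an adjusted p = 0.175 in fry, while those of the small subunit (Mrps, 8 of 29 fell) did not pass in camera (adjusted p = 0.0954). Small nucleolar RNA genes lie in introns of other genes, so reads from those introns leave their values uncertain. Of 35 Vps genes 16 rose and 2 fell, of 28 sorting nexins 13 rose and 1 fell, of 17 peroxins 8 rose, and of 8 Igsf genes 7 rose. Single genes chosen after their values were seen were Nfasc, from 643.6 ± 644 to 84200 ± 7550, Tubb4a, from 358.3 ± 178 to 37880 ± 2602, and the Igfbp genes, of which Igfbp3 and Igfbp4 fell by 3.96 and 5.52 and Igfbp5 rose by 2.68 (1.86 without EF 69). The log2 fold change of Nfasc was 7.49, and 8.27 without EF 68.

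The molecule is labelled as polyadenylated RNA, and mitochondrial ribosomal RNA took 5.61% to 9.9% of the recovered reads. The small nuclear RNA Rn7sk took 0.339% to 0.533% in EF and 0.777% to 0.797% in PDGFA.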
